A study of Mus musculus and Rattus norvegicus with 8 samples.

How the data were processed

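Total RNA from mouse and rat lung was, per the labels, reverse transcribed with an oligo-dT primer, amplified to biotinylated cRNA and hybridised to Affymetrix arrays, MG_U74Av2 for the mice and the rat array of the same maker for the rats. The deposited values are probe-set signal intensities on a linear scale, 1 column for each of the 8 arrays, and the values show a scaling of each array to a common mean by the authors: the 2% trimmed means were 150 on the mouse arrays and 149 to 150 on the rat arrays. No value was negative. The software, the scaling target and detection calls are not given in the sources used here, and the 8 experiment description files hold no measurement and were not used here. Groups were read from the sample titles: 2 controls and 2 ventilated samples in each species. The labels do not say more than that the replicates are separate samples, so the p of a single gene measures the spread between these samples. The main p of a gene list compares its genes with the other genes, and the p of an overlap is taken across genes. Neither of these measures the spread between samples.

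Probe sets were named with the supplied gene table of each array. In the mouse, 10833 of 12422 probe sets had 1 symbol, 396 had several and 1193 had none, giving 8251 genes. In the rat, 7006 of 8740 had 1 symbol, 308 had several and 1426 had none, giving 4736 genes. The mouse assembly GRCm38.p6 served for gene names and gene spans only. Control probe sets were left out of the mouse table, and the rat table holds none, so RNA quality ratios and spike-in signals exist for the mouse alone.

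Within each species the 4 arrays were quantile-normalised together, signals under the 25th percentile (14.2 in the mouse, 11.5 in the rat) were raised to it, and log2 was taken. Each gene was represented by its brightest probe set, and genes whose mean signal was not above the 25th percentile were left out. That left 6888 mouse and 3876 rat genes, and 2297 genes in both species, matched by symbol. Signals printed in the text are normalised and not raised to the floor. Ventilated and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The joint fit took species as a block, and the difference between species was the interaction of species and ventilation. No replicate number was used as a block, as the labels do not say what the numbers share.

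The 35 gene lists (pathways, and markers of lung and neighbouring cell types), the 26 sentinel genes, the thresholds, the comparisons and the rule for named genes were fixed before the data were examined. Lists with at least 4 tested genes were compared with all other genes by limma's camera at a preset correlation of 0.01, with the correlation estimated from the data as an alternative. The rotation test fry asked another question, whether a list's genes move one way on balance, without comparing them with other genes. A list's members overlap with other lists in places. The rule named, in each direction, the 10 genes with the largest change among those called whose ventilated arrays lay both beyond the controls, filled by smallest p where fewer passed; at most 4 members of each list by smallest p; the 5 smallest p of the interaction; and allowed any sentinel gene to be named. Genes outside this rule are said to have been chosen after their values were seen. The test of list differences between species was added after the data were seen.

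The pipeline was tested on simulated data with the arrays, spread and filters of the real data and 200 changed genes in each of 10 runs. Of genes changed 2-fold and 4-fold, 0% and 0% were recovered in the mouse, 30.5% and 73.1% in the rat, 62.1% and 94.2% in the joint fit, and 8% and 47.7% in the interaction, and 0 called genes had the wrong sign. A list shifted by 1 on the log2 scale was called in 10 of 10 runs at the preset correlation in every fit. With an estimated correlation it was called in 0 runs in the mouse, 0 in the rat, 9 in the joint fit and 2 in the interaction, and by fry in 1, 10, 9 and 6. Of unshifted lists, camera called 4 of 328 in the mouse, 2 of 317 in the rat, 4 of 309 in the joint fit and 1 of 305 in the interaction. The simulated genes varied independently of each other. Genes of some real lists did not, with an estimated correlation of 0.594 for mouse B and plasma cell markers, so these rates do not cover correlated lists.

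Alternatives were scaling to a common median, the values as deposited, cyclic loess, a floor at the 40th percentile or of 1, no filter or one at the 50th percentile, the mean of a gene's probe sets, all probe sets, other variance priors, an adjusted p under 0.10, the replicate number or the crossed numbers as a block, and each array left out in turn. Where an array is left out, its group has 1 array, which is assumed to vary like the other group. Agreement between species was described by correlations and by the overlap of the 100 largest changes, across genes.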

Results

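The series holds 8 lung RNA samples, each measured on 1 oligonucleotide array. Of the C57BL6 male mice, aged 7 to 8 weeks, 2 samples came from mechanically ventilated animals and 2 from animals breathing spontaneously. Per the labels, the mice received 17 ml/kg for 6 hours or 35 ml/kg for 2 hours, without saying which array had which regimen, so both ventilated arrays form 1 group. Of the male Wistar rats, aged 8 weeks, 2 samples came from animals ventilated with room air at 12 ml/kg for 5 hours and 2 from animals breathing spontaneously through a tracheal cannula of the same kind. Each mouse array gave signals for 12422 probe sets after 66 control probe sets were set aside, and each rat array gave signals for 8740. The median deposited signal ranged from 55.3 to 63.4 on the mouse arrays and from 42.6 to 46.2 on the rat arrays. Array signals have no counting depth, and the 2 arrays per group limit the precision of every value. The Pearson correlation of log2 signals between replicates, across the genes tested, was 0.935 for the mouse controls and 0.908 for the ventilated mice, against 0.967 for the rat controls and 0.977 for the ventilated rats. The highest value among the mouse arrays, 0.963, joined control 1 and ventilated 2, which belong to different groups.

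The mouse comparison asks which lung transcripts differed between large tidal volume ventilation and spontaneous breathing. Glucocorticoid-responsive genes rose as a list in ventilated mouse lung: 19 of 23 measured members were positive, with a median log2 change of 1.13 (limma camera, adjusted p = 2.84e-18; adjusted p = 0.254 with an estimated correlation). Immediate early genes, which cells switch on rapidly after a stimulus, rose as a list as well: 27 of 33 members were positive, with a median log2 change of 0.79 (adjusted p = 9.43e-17; adjusted p = 0.254 with an estimated correlation). Both ventilated arrays shared this shift. The list medians over the mean of the control arrays were 1.17 and 0.87 for the glucocorticoid-responsive genes, and 0.74 and 0.66 for the immediate early genes, on ventilated arrays 1 and 2. Interferon-stimulated genes fell as a list, with 22 of 23 members negative and a median log2 change of -0.44 (adjusted p = 2.45e-06; adjusted p = 0.475 with an estimated correlation), and list medians of -0.56 and -0.26 on ventilated arrays 1 and 2. These 3 calls held without any single array. With an estimated correlation, 0 of 10 shifted lists were called in simulated mouse data and 0 in simulated rat data. That setting therefore cannot decide on the mouse or rat lists.

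Single genes carried these lists without passing the test over all genes. Cebpd, a transcription factor gene of the acute phase response and a member of both rising lists, had a mean signal of 905 ± 8.24 (SD, n = 2) in controls and 2802 ± 19.9 (SD, n = 2) in ventilated mice, a log2 difference of 1.63 ± 0.21 (SE). Atf3, a stress-induced transcription factor gene, had a log2 difference of 1.62 ± 0.30 (SE), and Klf4, a shear-responsive factor of the endothelium, one of 1.06 ± 0.23 (SE). Atf3 was measured by 3 probe sets, whose log2 differences ranged from 0 to 2.65. The values for Maff and Gadd45g were 1.92 ± 0.40 and 1.52 ± 0.32 (SE), the former with 1 control array at the floor, on which its size depends. Of the sentinel genes in this list, Fos had a log2 difference of 0.62 ± 0.77 with its highest signal, 1096, on control 2, and Egr1 one of -0.36 ± 0.58 (SE). Edn1, which encodes the vasoconstrictor endothelin, had a value of 1.35 ± 0.29, the cell cycle inhibitor gene Cdkn1a one of 1.97 ± 0.36, and the kinase gene Pim3 one of 1.73 ± 0.38 (SE). Among glucocorticoid-responsive members, Errfi1, a feedback inhibitor of the EGF receptor, stood at 1.75 ± 0.39 (SE), and Tat, which encodes an amino acid enzyme of the liver, at 2.11 ± 0.39 with both controls at the floor, at least 4.31-fold higher. Adjusted over the list alone, 10 immediate early genes and 12 glucocorticoid-responsive genes were higher and none lower, against 0 of each over all genes. On the low side, the phospholipid scramblase gene Plscr2 had a log2 difference of -2.34 ± 0.40, the clock output gene Dbp one of -2.08 ± 0.56, Pigr, which encodes the immunoglobulin transporter of epithelia, one of -1.13 ± 0.30, and Sox18, an endothelial transcription factor gene, one of -0.81 ± 0.24 (SE). Epop stood at 2.11 ± 0.44 (SE). The sizes for Plscr2 and Dbp, each with 1 ventilated array at the floor, and for Epop, with 1 control array there, depend on the floor. Car3, Thrsp, Get4, Myt1l, Pcbp4 and Sox2 had log2 differences between -1.14 (Pcbp4) and -1.63 (Car3).

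**Figure D1:**
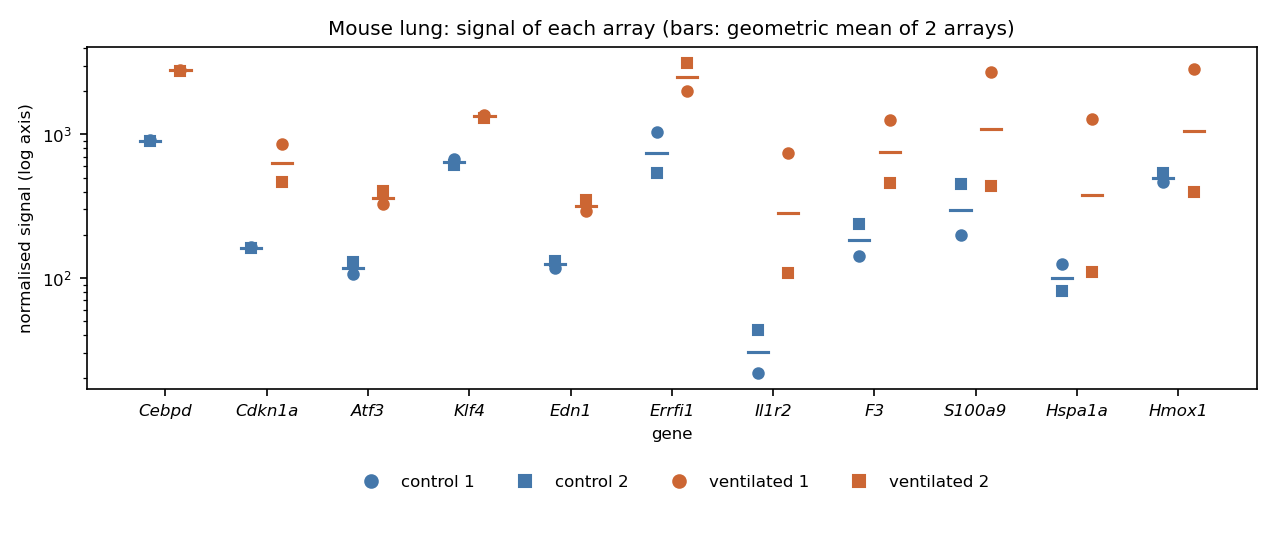
Normalised signal (log axis) of 11 named genes on the 4 mouse lung arrays, with bars at the geometric mean of each group. Cebpd, Atf3, Klf4 and Edn1 lie higher on both ventilated arrays, whereas S100a9, Hspa1a and Hmox1 are high on ventilated 1 alone; no single gene passed the test.

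Neutrophil, stress and hypoxia lists rose mainly through 1 ventilated array. Neutrophil markers had 17 of 18 members positive and a median log2 change of 0.78 (adjusted p = 6.51e-07; adjusted p = 0.475 with an estimated correlation), but their list median over controls was 1.54 on ventilated 1 and 0.18 on ventilated 2. The median over controls of monocyte and macrophage markers was 0.82 and -0.08 on these arrays, that of heat shock proteins 0.74 and 0.11, that of the unfolded protein response 0.63 and 0.18, that of hypoxia and glycolysis 0.71 and 0.16, and that of cytokine receptors and antagonists 0.80 and 0.13. These 5 lists passed with an adjusted p of 0.000421, 0.00045, 0.000225, 2.66e-05 and 0.000445 in that order, each with an adjusted p = 0.475 with an estimated correlation. Without ventilated 1 the adjusted p was 0.0682 for neutrophil markers, 0.802 with the opposite direction for monocyte and macrophage markers, 0.439 for heat shock proteins, 0.285 for the unfolded protein response, 0.306 for hypoxia and glycolysis and 0.439 for cytokine receptors and antagonists. Without control 1 it was 0.0633 for hypoxia and glycolysis and 0.0658 for monocyte and macrophage markers. S100a9, a calgranulin of neutrophils, had signals of 199 and 450 in controls and of 2744 and 440 in ventilated mice. Hspa1a, an inducible heat shock protein gene, had signals of 124 and 81.2 in controls and of 1291 and 111 in ventilated mice. Hmox1, the inducible heme oxygenase gene, had signals of 469 and 535 against 2851 and 395. Il1r2, the interleukin-1 decoy receptor gene, was higher on both ventilated arrays, at 740 and 109 against 21.6 and 43.1, as was the tissue factor gene F3, at 1262 and 456 against 143 and 239. On ventilated 1 the hybridisation spike-ins, which carry no lung RNA, were 2.62 times as bright as on the controls (median of 9 probe sets), against 0.96 times on ventilated 2. The p53 target and apoptosis list also passed (median log2 change 0.10, adjusted p = 0.0225; adjusted p = 0.475 with an estimated correlation), and 1 member, Cdkn1a, was higher adjusted over the list alone. That call was lost without ventilated 1 (0.0508), ventilated 2 (0.128) or control 1 (0.271).

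B cell, smooth muscle, cardiac and adipose markers fell as lists in ventilated mice. B and plasma cell markers had 14 of 15 members negative (median -0.66, adjusted p = 3.76e-05; adjusted p = 0.475 with an estimated correlation), among them Ms4a1, the CD20 gene, at -0.87 ± 0.47 and the immunoglobulin heavy chain gene Ighm at -0.78 ± 0.45 (SE). Smooth muscle and fibroblast markers had 17 of 18 negative (median -0.37, adjusted p = 0.000893; adjusted p = 0.513 with an estimated correlation). The smooth muscle actin gene Acta2 stood at -1.30 ± 0.72 (SE). Cardiac muscle markers had 18 of 20 negative (median -0.55, adjusted p = 0.00036; adjusted p = 0.475 with an estimated correlation), with the cardiac myosin gene Myh6 at -0.89 ± 0.28 (SE). Adipose and mesothelium markers had 7 of 11 negative (median -0.51, adjusted p = 0.0309; adjusted p = 0.475 with an estimated correlation), with the adiponectin gene Adipoq at -1.47 ± 0.54 (SE). Cardiac markers were highest on control 2, at 0.78 above the mean of all 4 arrays, and without that array their adjusted p was 0.895 with the opposite direction. Without control 2 the adjusted p was 0.0616 for B cell markers and 0.591 for adipose markers. Without ventilated 1 it was 0.306 for B cell markers and 0.818, with the opposite direction, for smooth muscle and fibroblast markers, and without control 1 it was 0.0962 for the latter. Without ventilated 2 it was 0.232 for cardiac and 0.323 for adipose markers. Genes chosen after their values were seen bear on control 1: Xist, the transcript of the inactive X chromosome, had a signal of 968 there against 6.48, 16.8 and 2.05 on control 2, ventilated 1 and ventilated 2, and the Y-linked gene Eif2s3y had 9.32 against 95.3, 61.8 and 138, although the labels give all mice as male.

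Over all 6888 mouse genes, limma called 0 at an adjusted p under 0.05, and 0 also without the variance trend and with the robust prior. At an unadjusted p under 0.05 there were 178 genes, 111 higher and 67 lower, where chance gives 344, and the smallest adjusted p was 0.9997. In simulated data of this size and spread, 0% of genes changed 4-fold were recovered, so changes of that size in single genes were not detectable here. By the rotation test fry, 0 of 35 lists passed, with a smallest adjusted p of 0.36.

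The rat comparison asks which lung transcripts differed between ventilation at a lower tidal volume and spontaneous breathing. Of 3876 genes, limma called 224, of which 96 rose and 128 fell. T and NK cell markers rose as a list (10 of 14 positive, median log2 change 2.42, adjusted p = 1.32e-06; adjusted p = 0.382 with an estimated correlation), with 9 members called higher and 1 lower. Thy1, a surface glycoprotein gene of rat thymocytes and fibroblasts, rose from a mean signal of 50.0 ± 14.0 to 1967 ± 357 (SD, n = 2 each), a log2 change of 5.32 ± 0.23 (SE; adjusted p = 0.000385). The T-cell receptor complex genes Cd3g and Cd3d rose by 4.41 ± 0.15 and 3.62 ± 0.17 on the log2 scale (SE; adjusted p = 0.000243 and 0.000474), Cd8a by 2.89 ± 0.16, the kinase gene Lck by 2.89 ± 0.30 and its adaptor Lat by 2.77 ± 0.21. The called member on the low side was Ccl5, a chemokine gene of activated T and NK cells, at -0.999 ± 0.14 (SE; adjusted p = 0.016).

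Adipose, muscle and liver transcripts rose in the ventilated rats too. The adipose and mesothelium list passed (5 of 9 positive, median log2 change 0.22, mean 1.10, adjusted p = 0.0134 and adjusted p = 0.382 with an estimated correlation), with 4 members called higher and none lower. Adjusted over the list alone, 4 members were higher and 1 lower. Ucp1, the uncoupling protein gene of brown fat, rose from 67.1 ± 11.5 to 1199 ± 23.6 (SD, n = 2 each), a log2 change of 4.17 ± 0.17 (SE; adjusted p = 0.000322). The lipid droplet gene Cidea rose by 2.32 ± 0.21, the fatty acid binding protein gene Fabp4 by 2.43 ± 0.16 and Cfd, the adipsin gene, by 1.68 ± 0.18 (SE). Gpd1, a glycerolipid enzyme gene, rose by 3.18 ± 0.25, and the stearoyl-CoA desaturase gene Scd, a member of the fixed alveolar type 2 list, by 2.49 ± 0.14 (SE). Cardiac muscle markers rose as a list (15 of 18 positive, median 0.35, adjusted p = 0.00462; adjusted p = 0.382 with an estimated correlation), with 4 members called higher. Among these were Cox8b, a respiratory chain gene also active in brown fat, at 1.98 ± 0.17 (SE), the natriuretic peptide gene Nppa at 1.73 ± 0.27 and the atrial myosin light chain gene Myl4 at 1.01 ± 0.14 (SE). The calcium pump gene Atp2a2 was called lower at -0.94 ± 0.14 (SE). Skeletal muscle markers passed as a list (12 of 15 positive, median 0.49, adjusted p = 0.0235; adjusted p = 0.382 with an estimated correlation) with none called singly. Hepatocyte markers rose as a list (11 of 12 positive, median 0.77, adjusted p = 0.000591; adjusted p = 0.382 with an estimated correlation), with 3 called higher over all genes and 5 adjusted over the list alone, among them Ttr and Rbp4, which encode plasma transport proteins. These rose by 1.58 ± 0.22 and 1.56 ± 0.14 (SE).

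**Figure D2:**
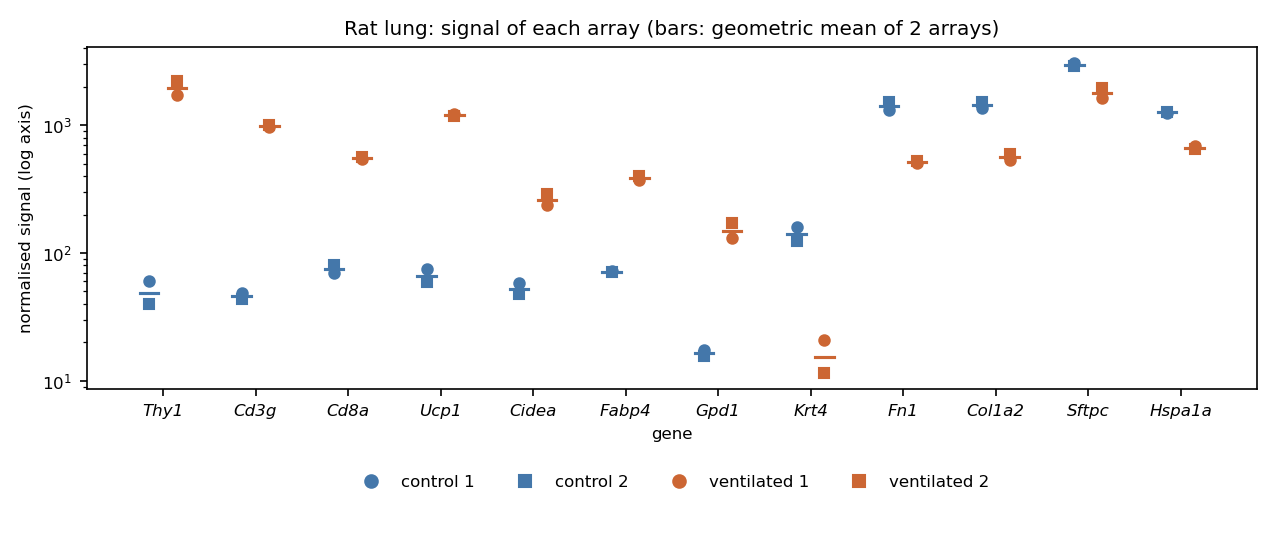
Normalised signal (log axis) of 12 named genes on the 4 rat lung arrays, with bars at the geometric mean of each group. T-cell genes (Thy1, Cd3g, Cd8a) and adipose genes (Ucp1, Cidea, Fabp4, Gpd1) are higher on both ventilated arrays, and matrix genes (Fn1, Col1a2), Krt4, Sftpc and Hspa1a are lower.

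Matrix, smooth muscle, endothelial and alveolar type 2 lists fell in ventilated rats. Smooth muscle and fibroblast markers fell as a list (13 of 17 negative, median -0.38, adjusted p = 0.000336; adjusted p = 0.382 with an estimated correlation), with 7 called lower, among them the smooth muscle myosin gene Myh11 at -1.53 ± 0.16 and the pericyte proteoglycan gene Cspg4 at -1.36 ± 0.21 (SE). The extracellular matrix and protease list fell (17 of 29 negative, median -0.25, adjusted p = 0.0134 and adjusted p = 0.418 with an estimated correlation), with 10 called lower. Adjusted over the list alone, 11 of its members were lower and 3 higher. Fn1, the fibronectin gene, fell from 1419 ± 140 to 514 ± 9.99 (SD, n = 2 each), and the collagen gene Col1a2 had a log2 change of -1.37 ± 0.12 (SE). Fn1 was measured by 5 probe sets, whose log2 changes ranged from -1.72 to 0.21. Endothelial markers fell as a list (10 of 11 negative, median -0.40, adjusted p = 0.0102; adjusted p = 0.418 with an estimated correlation), with the angiotensin-converting enzyme gene Ace called at -0.89 ± 0.18 (SE). Alveolar type 2 and surfactant markers fell (10 of 11 negative, median -0.33, adjusted p = 0.0235; adjusted p = 0.382 with an estimated correlation), with the surfactant protein C gene Sftpc at -0.73 ± 0.12, the lung transcription factor gene Nkx2-1 at -1.33 ± 0.14 and the mucin gene Muc1 at -1.003 ± 0.144 (SE). The largest change in this list went the other way, in its member Scd, called higher at 2.49 ± 0.14 (SE). The lists of alveolar type 1 (adjusted p = 0.143) and of club and ciliated cells (adjusted p = 0.781) did not pass. Vascular tone genes fell as a list (16 of 20 negative, adjusted p = 0.0242), with the endothelin-converting enzyme gene Ece1 at -1.03 ± 0.14 (SE), as did ion and water transport genes (11 of 15 negative, adjusted p = 0.0134), with the epithelial sodium channel gene Scnn1a at -1.26 ± 0.12 (SE). Both lists had an adjusted p = 0.382 with an estimated correlation. Across genes, which are not independent replicates, the rat log2 change correlated with the genomic span of the mouse gene of the same symbol, known for 95.7% of rat genes, at a Pearson r of -0.223, against -0.03 for the mouse log2 change. The median rat log2 change was 0.085 in the fifth of genes with the shortest span and -0.190 in the fifth with the longest. The falls above were not separated from this trend, and RNA quality could not be measured on the rat arrays. Nor were they separated from the rises of T-cell and adipose transcripts on the same arrays, for which carried-over tissue stays open.

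Interferon-stimulated and proliferation genes rose in ventilated rats. Interferon-stimulated genes rose as a list (11 of 14 positive, median 0.47, adjusted p = 0.0134; adjusted p = 0.382 with an estimated correlation), with Rsad2, the viperin gene, at 1.47 ± 0.16 and the immunoproteasome genes Psmb8 and Psmb9 at 0.82 ± 0.16 and 0.70 ± 0.14 (SE). Proliferation genes rose as a list (15 of 18 positive, median 0.52, adjusted p = 0.000502; adjusted p = 0.382 with an estimated correlation), with Pcna, the replication clamp gene, called at 0.65 ± 0.12 (SE) and 9 members higher adjusted over the list alone. The T and NK cell markers, with a median of 2.42, rose on the same arrays. Il6, an acute phase cytokine gene, was at least 3.56-fold higher, as both controls lay at the floor (adjusted p = 0.0208), and the monocyte chemoattractant gene Ccl2 rose by 1.20 ± 0.18 (SE; adjusted p = 0.0202). The alarmin gene S100a8 rose by 0.58 ± 0.11 (SE), while the neutrophil list did not pass (7 of 8 positive, adjusted p = 0.147). Glucocorticoid-responsive genes fell as a list (12 of 15 negative, median -0.37, adjusted p = 0.0134; adjusted p = 0.382 with an estimated correlation), with Scnn1a, which is also in the ion transport list, called lower, and with 5 members lower and 1 higher adjusted over the list alone. Immediate early genes did not pass (19 of 27 negative, adjusted p = 0.354), with Zfp36 and Klf4 called at -0.74 ± 0.14 and -0.63 ± 0.13 (SE). The heat shock gene Hspa1a fell by 0.91 ± 0.11 on the log2 scale (SE; adjusted p = 0.0117). Among the largest falls, the keratin gene Krt4 had a log2 change of -3.19 ± 0.34, Slit3, a guidance cue gene, one of -2.36 ± 0.39 and Ltbp2, a latent TGF-beta binding protein gene, one of -2.35 ± 0.29 (SE). Arhgap39, Wdfy3, Sf3b1, the spectrin gene Sptan1 and the dynein heavy chain gene Dync1h1 were also called, with log2 changes between -2.17 (Arhgap39) and -1.77 (Dync1h1). Krt4 and Sf3b1 each had 1 ventilated array at the floor, on which the sizes of their changes depend. Pcnx3 and Lrrc8a were called too, at least 5.03-fold and 4.24-fold lower, with both ventilated arrays at the floor. The basal keratin gene Krt5 was at least 7.83-fold higher, with both controls at the floor, and the defensin gene RatNP-3b rose by 3.19 ± 0.23 (SE).

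Without any 1 of the 4 rat arrays limma called 0 genes, with 543 to 864 genes at an unadjusted p under 0.05, against 979 in the full set, where chance gives 194. Among the genes with the largest changes and the sentinel genes, 0 of those called changed direction in these fits. The rule had chosen the former with both ventilated arrays beyond the controls, so this outcome was nearly fixed and adds no support. The count of 224 became 23 with a floor at the 40th percentile, 39 with no filter on dim genes, 61 without the variance trend, 146 with the replicate number as a block, 395 over all probe sets, 479 at an adjusted p under 0.10 and 257 under median scaling, where 60.3% of the called genes were higher. The list calls for T and NK cells, hepatocytes, proliferation, cardiac muscle, interferon-stimulated genes and smooth muscle and fibroblasts held without any single array. Without control 2 the adjusted p was 0.115 for the extracellular matrix list, 0.0761 for the glucocorticoid-responsive, ion transport and adipose lists, 0.285 for alveolar type 2 markers and 0.0534 for skeletal muscle and vascular tone. Without control 1 it was 0.218 for alveolar type 2 markers, 0.134 for endothelial markers and 0.111 for vascular tone, and without ventilated 1 it was 0.0795 for alveolar type 2 markers, 0.197 for skeletal muscle and 0.0508 for vascular tone. Without ventilated 2 it was 0.072 for the extracellular matrix list.

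**Figure D3:**
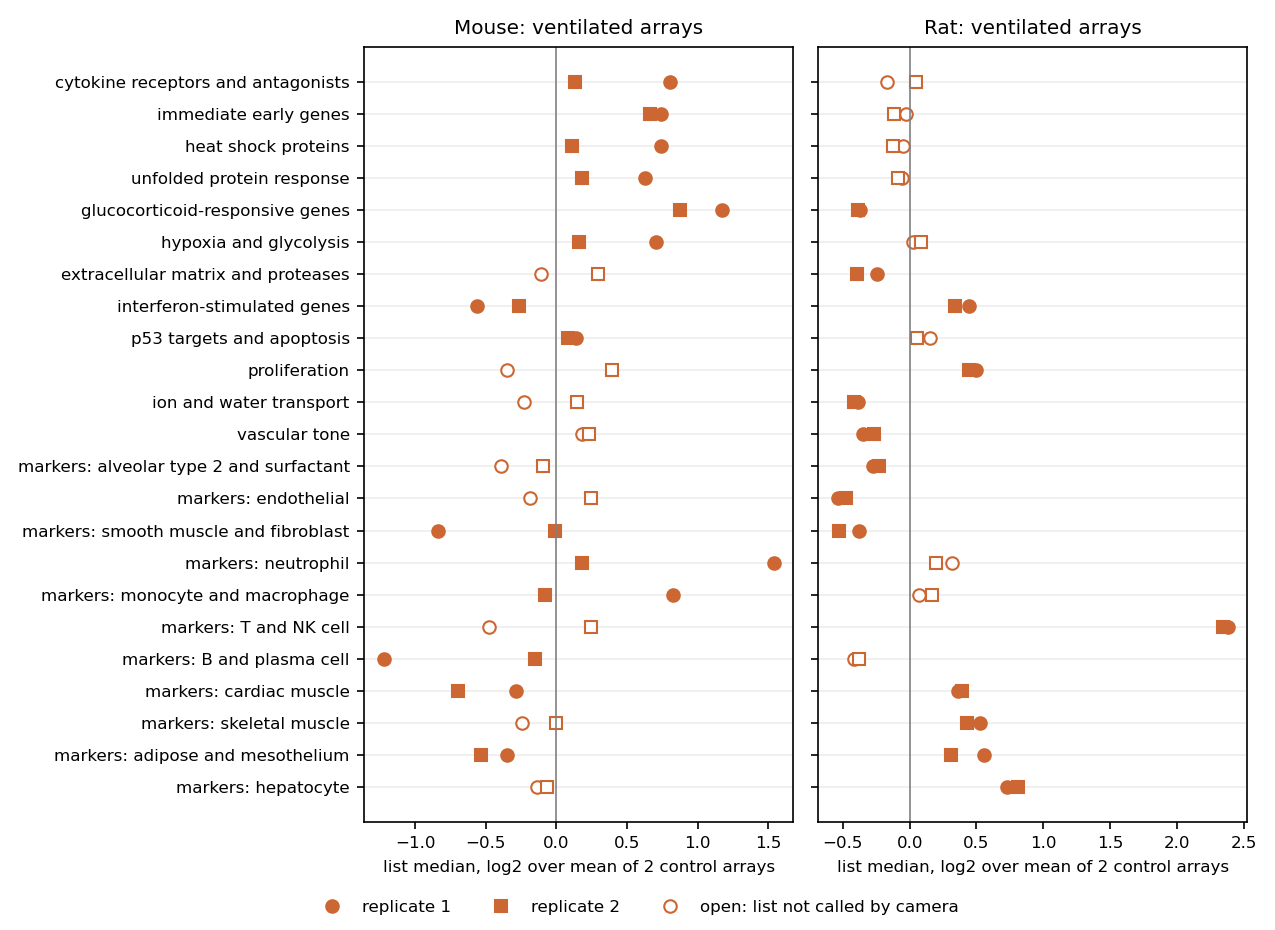
Median log2 signal of each gene list on each ventilated array over the mean of the 2 control arrays, for the lists called in either species; open symbols are lists not called in that species. The 2 mouse arrays differ most for neutrophil markers (1.54 and 0.18), and the 2 rat arrays lie close together, as for T and NK cell markers (2.38 and 2.34).

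The joint comparison asks which genes changed on average over both species, with species as a block, over 2297 genes measured on both array types. It does not test that the species moved alike. Immediate early genes rose as a list (19 of 22 positive, median log2 change 0.30, adjusted p = 0.00117) and so did neutrophil markers (8 of 8, median 0.89, adjusted p = 0.00257), while smooth muscle and fibroblast markers (14 of 15 negative, median -0.34, adjusted p = 0.00117) and B and plasma cell markers (4 of 4 negative, median -0.61, adjusted p = 0.0279) fell. Each had an adjusted p = 0.718 with an estimated correlation. The immediate early genes were 27 of 33 positive in mice but 19 of 27 negative in rats, and their response differed between the species (adjusted p = 2.69e-07; adjusted p = 0.121 with an estimated correlation), as did that of the neutrophil markers (adjusted p = 0.0192; adjusted p = 0.560 with an estimated correlation). Without mouse ventilated 1 the adjusted p was 0.101 for immediate early genes, 0.262 for neutrophil markers, 0.117 for smooth muscle and fibroblast markers and 0.152 for B cell markers. Without mouse control 1 it was 0.101, 0.0943 and 0.0709 for immediate early genes, neutrophil and B cell markers, and without mouse control 2 it was 0.096 for B cell markers. Atf3 had the smallest p among higher genes, with a joint log2 change of 1.11 ± 0.25 (SE), from 1.62 in mice and 0.59 in rats. Phgdh, a serine synthesis gene, stood at 0.87 ± 0.21, Ninj1, a membrane rupture gene, at 0.98 ± 0.26, Ifrd1 at 1.03 ± 0.29 and the cAMP-responsive gene Crem at 0.98 ± 0.28 (SE). On the low side, Aco1 stood at -0.86 ± 0.21, the endothelial receptor gene Acvrl1 at -0.70 ± 0.17, Muc1 at -0.74 ± 0.19 and Myh11 at -1.02 ± 0.26 (SE). None of these passed: limma called 0 of 2297 genes, the smallest adjusted p was 0.64, and 178 genes had an unadjusted p under 0.05, 85 higher and 93 lower, where chance gives 115. The count was 0 also without the trend and with the robust prior, and fry called 0 lists. In simulated data the joint fit recovered 94.2% of genes changed 4-fold and 62.1% of genes changed 2-fold in both species.

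Where the species' responses differed was tested as the interaction of species and ventilation. The change in rats minus that in mice was positive for the desaturase gene Scd1, named Scd in rats, by 2.66 ± 0.27 (SE; adjusted p = 0.0121), for Gpd1, by 3.57 ± 0.38 (adjusted p = 0.0121), and for Cd3d, by 3.26 ± 0.50 (adjusted p = 0.0474). It was negative for Krt4 at -3.87 ± 0.50, Cebpd at -2.00 ± 0.27, Klf4 at -1.69 ± 0.25 and Dync1h1 at -1.92 ± 0.29 (SE; adjusted p from 0.0322 to 0.0474). These 7 genes, 3 positive and 4 negative, were all that limma called, with 294 at an unadjusted p under 0.05. Dync1h1 and Cd3d, outside the 5 with the smallest p, were named after their values were seen. Immediate early genes differed as a list (19 of 22 more negative in rats, adjusted p = 2.69e-07; adjusted p = 0.121 with an estimated correlation), as did glucocorticoid-responsive genes (13 of 14, adjusted p = 3.19e-05; adjusted p = 0.121 with an estimated correlation). Vascular tone genes, endothelial and neutrophil markers and cytokine receptors were also more negative in rats, and cardiac, hepatocyte, T and NK cell markers and interferon-stimulated genes more positive, all 8 with adjusted p values between 5.73e-05 and 0.0393, and from 0.276 to 0.560 with an estimated correlation. No list passed with an estimated correlation, and fry, which does not compare a list with other genes, called 4. The calls for immediate early, glucocorticoid-responsive and interferon-stimulated genes and for cardiac and hepatocyte markers held without any single array. The adjusted p was 0.0746 for T and NK cell markers without mouse control 1, 0.111 for vascular tone and 0.125 for endothelial markers without mouse ventilated 2, and 0.637 for neutrophil markers and for cytokine receptors without mouse ventilated 1. Without mouse control 2 it was 0.0643 for vascular tone and endothelial markers and 0.0695 for cytokine receptors, and without mouse control 1 it was 0.157 for neutrophil markers and 0.0755 for cytokine receptors. Without rat control 1 it was 0.0987 for endothelial markers and cytokine receptors and 0.0666 for neutrophil markers, and without rat ventilated 1 it was 0.0939 for cytokine receptors. The gene count was 0 without mouse control 1 and without each of the 4 rat arrays, 2 without mouse control 2, 22 without mouse ventilated 1 and 84 without mouse ventilated 2, and it was 0 with the replicate number as a block, 3 without the variance trend, 14 with a floor at the 40th percentile and 23 with no filter on dim genes. Species, array type, strain, tidal volume and duration differ together here and cannot be told apart. The rat controls breathed through a tracheal cannula, while the mouse controls are described only as breathing spontaneously, so control handling may differ as well.

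Across the 2297 shared genes, which are not independent replicates, the log2 changes of the species had a Pearson correlation of -0.041 and a Spearman correlation of -0.024, and 50.0% of genes had the same sign. The correlation was -0.107 without mouse control 1, -0.106 without mouse ventilated 1, 0.033 without mouse control 2 and 0.014 without mouse ventilated 2. Of the 100 genes with the largest rise in each species 1 was shared, the chemokine gene Xcl1, and of the 100 with the largest fall 2 were shared, the B-cell receptor gene Cd79b and Ndn, where chance gives 4.35 (two-sided Fisher's exact test across genes, p = 0.127 and 0.32). These 3 genes were named after their values were seen. With 0 mouse genes called, no gene was called in both species.

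**Figure D4:**
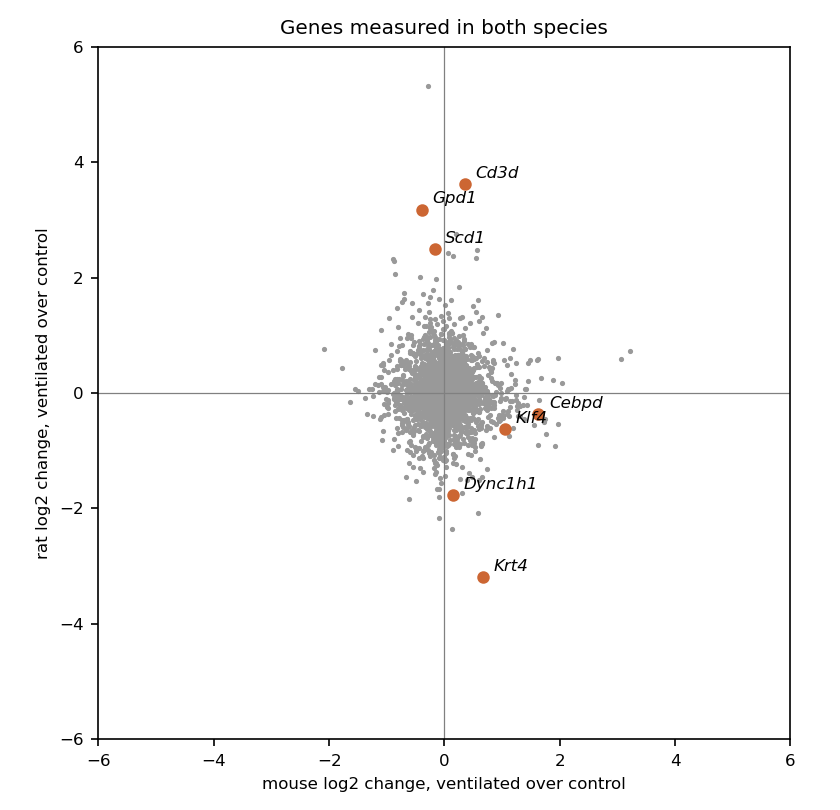
Log2 change of ventilated over control lung in mice (x axis) and rats (y axis), 1 point per gene, for 2297 genes. The 7 genes whose response differed between species are named, and the points show no common trend (Pearson correlation across genes -0.041).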

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

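The 7 tests on the 3 patterns below, and the test of list differences between species, were chosen only after the results were seen. The counts over other splits of the arrays were planned.

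T-cell and adipose transcripts were higher in ventilated rats, and the rat change minus the mouse change was 3.26 for Cd3d and 3.57 for Gpd1 by the interaction test; the T and NK cell list differed too (adjusted p = 0.0117; adjusted p = 0.524 with an estimated correlation, and 0.0746 without mouse control 1), while the adipose and mesothelium list did not pass (adjusted p = 0.159). Lymphocytes of all kinds from blood are argued against by the 8 B-cell, NK and cytotoxic genes of the fixed lists, whose median log2 change was -0.34 while the 9 T-cell genes lay between 2.34 and 5.32. Fat tissue carried over with the lung stays open and cannot be told apart from a change within the lung. The 7 adipose genes had a median log2 change of 1.68, with 4 over 1 and Lep, Lpl and Pck1 not, and lung expresses some of these genes itself. Those over 1 include the brown-fat gene Ucp1 at 4.17 and Cidea at 2.32. The test took adipose genes of all kinds together, so it cannot decide on brown fat alone. Thymus, which borders the lung beside brown fat, cannot be told apart either. Only 2 further thymocyte genes passed the signal filter, Cd4 at 0.31 and Cd1d1 at 0.75, with a median of 0.53, too few to decide. Rag1 lay under the floor on all 4 rat arrays. The T-cell genes were left out of this test, among them Thy1 at 5.32 and Cd8b, a member of the thymus list, at 2.37. Ventilation itself, the difference the design names, stays open and untested, and the median of the T-cell genes was at least 2.87 under 4 normalisations.

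Matrix genes chosen after their values were seen stood high on mouse control 1 and ventilated 2, which belong to different groups: the elastin gene Eln had signals of 6841 and 7419 there against 1461 and 1143 on control 2 and ventilated 1, and Col1a1 had 3200 and 3460 against 1128 and 501. Other genes chosen in this way parted the same arrays. The proliferation gene Mki67 had 92.55 and 113 against 28.0 and 25.8. Igha went the other way, at 54.1 and 52.4 against 707 and 506, as did Jchain, at 27.2 and 21.4 against 194 and 98.1. A female animal behind control 1, where Xist had a signal of 968, is argued against as the source of this pattern, since Xist on ventilated 2 was 2.05; a female or mixed sample behind control 1 alone remains open. RNA quality cannot be told apart from a difference in the tissue taken: the Gapdh 3' over 5' ratios were 2.96 and 2.48 on control 1 and ventilated 2 against 1.16 and 1.53 on the others, so the lower of the first pair was 1.62 times the higher of the second, and transcript lengths were not tested. The beta-actin ratios lay closer together, at 2.18 and 2.21 against 1.88 and 1.80. No biological explanation was tested, as no group of the design joins these arrays. The labels give the age of the mice as a range of weeks, without assigning ages to arrays. A difference in age between the arrays therefore stays open and untested.

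Neutrophil and stress transcripts as lists stood higher on mouse ventilated 1 than on ventilated 2, although Il1r2 was above both controls on each; ventilated 1 is the array whose hybridisation spike-ins, a signal outside the comparisons, were 2.62 times those of the control arrays. Less labelled RNA on that array cannot be told apart from a change in the lung: the 18 neutrophil genes exceeded those on ventilated 2 by a median of 1.37 on the log2 scale, but they define the pattern, and normalisation holds the median over all genes near 0 (-0.02). More blood left in that lung cannot be told apart from cells that entered the tissue, as the erythroid list had a median difference of -0.28 but 3 of its 7 genes were over 0.5. Of red-cell genes chosen after their values were seen, Hba-a1 had signals of 5897 and 7154 on ventilated 1 and 2. Alas2 had 242 and 1054 there. The labels name 2 ventilation regimens without assigning them to arrays, and a difference in regimen stays open and untested.

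Differences between the species, each by the interaction test, also include Scd1, a member of the fixed alveolar type 2 list, at 2.66, Krt4 at -3.87, Cebpd at -2.00, Klf4 at -1.69 and Dync1h1 at -1.92 (rat change minus mouse change, log2). By list, the adjusted p of the difference was 2.69e-07 for immediate early genes, 3.19e-05 for glucocorticoid-responsive genes, 5.73e-05 for cardiac muscle markers, 0.000361 for interferon-stimulated genes, 0.00533 for hepatocyte markers, 0.0152 for endothelial markers, 0.0192 for vascular tone, 0.0192 for neutrophil markers and 0.0393 for cytokine receptors and antagonists. With an estimated correlation none passed, with an adjusted p = 0.121 for the immediate early and glucocorticoid-responsive lists and an adjusted p from 0.276 to 0.560 for the others. Among rat probe sets without a gene name, which the comparisons leave out, 55 of 931 were called, 26 higher and 29 lower.

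The arrays can be split within each species in 18 ways, too few for a share under 0.05. The joint fit called 0 genes in the real split and up to 6 in another; with a real count of 0, the number of splits that give as many decides nothing. The interaction called 7 genes against up to 104, with 3 splits at least as large, the real one included, and the split with 104 keeps the rat groups and parts mouse control 1 and ventilated 2 from the other mouse arrays. A count that high points to a structure of the samples, but the other splits with this mouse parting gave 0 to 8 genes, and the cause was not tested. The joint lists called were 4 against up to 10, with 13 splits at least as large, and the correlation between species was -0.041 against 0.12 in the split farthest from 0, with 4 splits at least as far.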

How the results depend on the processing

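The crossed blocks, the list differences and the counts without marker genes were chosen after seeing the data; the other alternatives were planned, and a scan-date block was not run. Mouse and joint genes numbered 0 under every alternative run. The joint fit was not run over all probe sets. The rat count of 224 became 23 with a floor at the 40th percentile, 39 with no filter on dim genes, 61 with eBayes without a trend, 146 with the replicate block, 395 over all probe sets (more features tested) and 479 at an adjusted p under 0.10 (a looser threshold). Each rat array left out gave 0 to 0 genes. Median scaling gave 257, of which 60.3% were higher, and 189 were counted without the marker genes of T cells and of tissues next to the lung. The 7 genes differing between species became 11 with median scaling, 14 with a floor at the 40th percentile, 23 with no filter on dim genes, 13 with a filter at the 50th percentile, 3 with eBayes without a trend, 4 with trend and robust, 27 at an adjusted p under 0.10 and 0 with the replicate block, and ranged from 0 to 84 with 1 array left out. With crossed pairing as a block it was 34 genes, and 232 in the rat; deviations of same-numbered arrays correlated at -0.285 in the mouse and -0.106 in the rat.

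With an estimated correlation 0 mouse, 0 rat and 0 joint lists passed. In simulated data that setting found the shifted list in 0 of 10 mouse and 0 of 10 rat runs, so it cannot decide there. With fry 0 mouse and 0 joint lists passed, and 12 rat lists. These 12 included the cytokine, p53, alveolar type 1, and club and ciliated lists, which camera had not called. Camera, not fry (adjusted p from 0.0645 to 0.179), called the glucocorticoid-responsive, matrix, ion transport, alveolar type 2, endothelial and skeletal muscle lists. With 1 array left out, rat lists ranged from 7 to 13, joint lists from 2 to 7 and the correlation between species from -0.107 to 0.033. In mice the adjusted p then ranged from 2.30e-10 to 0.895 for cardiac muscle, 7.50e-06 to 0.818 for smooth muscle and fibroblast and 2.31e-07 to 0.802 for monocyte and macrophage markers, each highest value with the direction reversed. Under other scalings 0 calls of named rat genes were lost or reversed. Of 123 rat values 3 moved by at least the standard error of their log2 change, and of 123 mouse values 5, all of genes not called. Fits with 1 array left out rest on fewer arrays, and the lone array of a group is assumed to vary like the other groups. For every shift without a stated reason the cause was not tested. A floor near the signal of dim genes limits what can be seen among them.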

Other observations

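Lists that did not pass in the mouse held members with large differences, none of which passed over all genes. Among coagulation genes (14 of 23 positive, adjusted p = 0.0757), Plaur, the urokinase receptor gene, had a log2 difference of 1.64 ± 0.38, and Plat, the tissue plasminogen activator gene, one of 1.24 ± 0.43 (SE, n = 2 per group). Clock genes (adjusted p = 0.0757) included Nfil3 at 2.29 ± 0.53 and Per1 at 1.57 ± 0.50 against Dbp at -2.08 ± 0.56 (SE), with 1 ventilated array at the floor. The NF-kappaB inhibitor gene Nfkbia, also a glucocorticoid-responsive gene, stood at 1.13 ± 0.27 (SE) in a list with an adjusted p of 0.133. Of the chemokine genes, in a list with an adjusted p of 0.101, Cxcl2 was at least 2.52-fold higher, with both controls at the floor, and Cxcl1 stood at 1.13 ± 0.49 (SE) with 1 control at the floor. The metallothionein genes Mt1 and Mt2 stood at 1.99 ± 0.77 and 1.84 ± 0.67 (SE), with signals of 3674 and 725 for Mt1 on ventilated 1 and 2. Genes chosen after their values were seen were high on ventilated 1 alone: the neutrophil collagenase gene Mmp8 had a signal of 1005 there against 8.17 on ventilated 2, Saa3, an acute phase gene, 942 against 42.8, and Srxn1, an antioxidant gene, 963 against 56.1.

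In the rat, genes of lists that did not pass were called singly by limma. Pdk1, a kinase gene that curbs pyruvate oxidation, rose by 1.79 ± 0.27, the growth factor gene Vegfa had a log2 change of -0.68 ± 0.13, and the death agonist gene Bid rose by 1.33 ± 0.27 (SE). Sod2, the mitochondrial superoxide dismutase gene, rose by 0.79 ± 0.16 and the phospholipase gene Pla2g2a by 0.83 ± 0.14, while the thrombin receptor gene F2r stood at -0.75 ± 0.10 and the clock gene Per2 at -1.12 ± 0.23 (SE). The cytokine and chemokine list did not pass (11 of 20 positive, adjusted p = 0.599), nor did the thymus and lymph node list, whose median of -0.42 and mean of 0.18 differ in sign (adjusted p = 0.804). Its 2 positive members were Cd8b at 2.37, called singly, and Cd1d1 at 0.75. The 4 negative ones included Glycam1 at -0.63 and Madcam1 at -0.47. As its members moved in opposite directions, the list does not decide on thymus. Of the 224 called genes, 64 belonged to at least 1 fixed list.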
